A study of Mus musculus with 6 samples.

How the data were processed

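CD4 T cells from spleens and lymph nodes of C57BL/6 mice were activated for 48 h on plate-bound antibodies against CD3 and CD28, with no added cytokines, per the labels' protocols. RNA was depleted of ribosomal RNA and made into strand-specific Illumina libraries, per the labels' protocols. The 6 libraries fall into 2 genotypes of 3: controls carrying floxed Prmt5 alleles (replicates 1, 2 and 4) and knockouts carrying deleted Prmt5 alleles (replicates 1, 4 and 5). The series states that these are biological replicates. The title of knockout 4 also ends in R2, and what this stands for is not given in the sources used here. Groups were taken from the genotype label of each sample, iCD4-PRMT5fl/fl for controls and iCD4-PRMT5delta/delta for knockouts. The columns of the table were matched to samples by the sample titles.

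The deposited table holds raw read counts per gene for each library, and its column names mark them as raw. STAR, featureCounts, DESeq2 and DESeq, with the mouse build GRCm38.p3, are named per the submitters' processing notes, without role, order or version. The authors also deposited a normalized signal for 19941 genes, which is the raw count divided by a single size factor per library; it was checked against the raw counts and not used in any test. The deposited log2 fold changes of the authors' own comparison are control over knockout. The deposited adjusted p-values of that comparison carry no named adjustment method, and which tool made them is not given in the sources used here. A further 12 columns of per-sample values were not used here.

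The table has 54532 gene rows and 92 rows of ERCC spike-in RNAs, which were kept out of library sizes and tests. Of the gene identifiers, 53315 matched GENCODE release M21 for GRCm38 exactly, and coordinates come from that annotation. Where a symbol had several identifiers, the identifier with the most counts was used. Gene counts per library summed to between 29623513 and 39832588.

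All tests started from the raw counts. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 15685 genes, scaled with TMM factors and fitted with glmQLFit on genotype. The genotype coefficient was tested two-sided with glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are knockout over control, their standard errors (SE) are the fold change divided by the square root of the F statistic, and CPM values use TMM library sizes. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over all lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. R 4.3.3 was used, with version 1.17.8 of its data.table package.

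The design, the lists, the rule for named genes and the other tools and settings named below were fixed before the data were examined. The column names carry a tag that splits the libraries into batch A (control 1, control 2 and knockout 1) and batch B (control 4, knockout 4 and knockout 5). What the tag stands for is not given in the sources used here. The fit with this batch as a term beside genotype, the fits inside each batch, the scaling to ERCC counts and the fits without knockouts 1 and 5 were chosen after seeing the data.

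The functional lists were the PRMT family and methylosome, cholesterol biosynthesis, sterol sensing and uptake, fatty acid synthesis, LXR targets and cholesterol efflux, Th17, Th1, Th2, Treg, T cell activation, naive and quiescence, common gamma chain cytokine signalling, DNA replication and G1/S, G2/M and mitosis, p53 targets, spliceosomal Sm proteins and their assembly, glycolysis, amino acid and ATF4 response, oxidative phosphorylation, and interferon-stimulated genes. The marker lists covered CD4 T cells, CD8 T cells, NK cells, B cells, macrophages and monocytes, dendritic cells, neutrophils, erythroid cells, platelets, stroma and endothelium, and the sex of the animal.

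Named genes followed a fixed rule. It took Prmt5, then the 10 genes with the largest increase and the 10 with the largest decrease among genes past adjusted p 0.05 with a mean of at least 5 CPM, all knockouts on the same side of all controls and an established symbol. It took the 3 members of each functional list with the smallest p (6 for cholesterol biosynthesis and Th17), 11 genes named by symbol, and the most abundant tested member of each marker list. Some genes selected by this rule are not reported here; they were kept in every test and list and were not replaced. Because no gene passed in the fit on genotype alone, the rule for the largest changes was applied to the fit with the batch term. Further list members are named where 5 or fewer members of a list passed with the batch term. Srebf1, Tbx21, Gata3, Nfil3, Klf3, Bach2, Nusap1, Pfkp, Ndufs3, Klrk1 and Pax5 were chosen in this way after their values were seen, as were the library-level values of B cell, dendritic cell and Y-linked markers. Fasn and Acaca, outside this rule, were also named after their values were seen.

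The fits were repeated with DESeq2 1.42.0, limma-voom with and without sample quality weights, RLE and upper-quartile factors, no low-count filter, a filter of 1 CPM in all libraries of a genotype, the replicate number as a block, each library left out in turn, a test against a fold change of 1.5 and a threshold of 0.01.

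Both fits were tested on counts simulated from gene means and library sizes, with changes planted in genes of at least 5 CPM. The means were taken over all libraries for genotype alone and within each batch for the batch term. The simulation for genotype alone thus held no shared difference between the batches. With genotype alone, 23% of 100 genes changed 2-fold and 90% of 100 genes changed 4-fold were recovered among 15446 genes, with 6 false calls. This recovery does not show what that fit can detect in the real libraries, where 0 genes passed. With the batch term, 89% and 100% were recovered among 15442 genes, with 13 false calls. Those counts were drawn gene by gene from the same model that was then fitted. The recovery therefore does not show whether the batch-term calls in the real libraries would recur.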

Results

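Gene expression was measured by RNA sequencing in activated CD4 T cells, the helper lymphocytes that respond to antigen shown on class II molecules. The genotype labels were iCD4-PRMT5fl/fl, with floxed alleles of Prmt5 (controls, n = 3), and iCD4-PRMT5delta/delta, with deleted alleles (knockouts, n = 3). All cells were activated for 48 h through CD3 and CD28. Prmt5 encodes the main enzyme for symmetric dimethylation of arginine in proteins. The comparison asks which transcripts depend on Prmt5 in activated helper T cells, and the title of the series points to cholesterol synthesis and the Th17 programme. Gene counts per library ranged from 29623513 in knockout 1 to 39832588 in control 4.

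Prmt5 (ENSMUSG00000023110.12, chromosome 14, positions 54507187 to 54517525 on the minus strand of GRCm38) was lower in every knockout than in every control. Its level was 134, 133 and 98.2 CPM in controls 1, 2 and 4, against 41.1, 34.2 and 36.7 CPM in knockouts 1, 4 and 5. The group means were 121 ± 20.2 and 37.4 ± 3.50 CPM (SD, n = 3 each). The log2 fold change was -1.70 (SE 0.17), with an adjusted p of 0.109 by the edgeR quasi-likelihood test on genotype alone, which no other gene undercut. With the library batch as a term, Prmt5 fell by 1.58 on the log2 scale (SE 0.09, edgeR adjusted p = 0.00312). The difference was -1.69 inside batch A and -1.47 inside batch B. Counts cover the whole gene, so the deleted part was not resolved. In the authors' deposited table the log2 fold change of Prmt5, control over knockout, was 1.71 with an adjusted p of 1.2e-28.

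**Figure D1:**
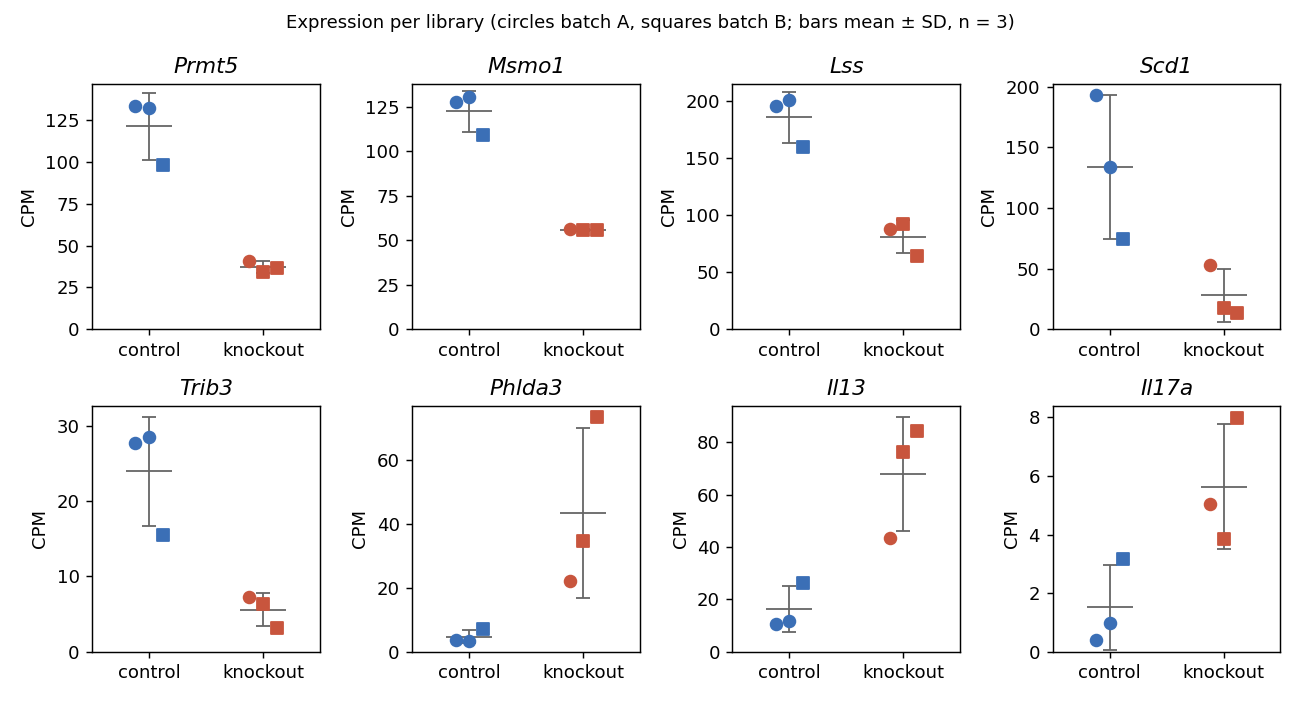
Expression of 8 named genes in CPM, on linear axes from 0, with a point for each library (blue controls, red knockouts, circles batch A, squares batch B) and bars for the mean ± SD of 3 libraries. Prmt5 lies between 98.2 and 134 CPM in controls and between 34.2 and 41.1 CPM in knockouts, and Msmo1 averages 123 CPM in controls and 55.9 CPM in knockouts.

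The libraries differed more between batches than between genotypes. Srebf2, which encodes the transcription factor that drives sterol synthesis genes, stood at 295 and 227 CPM in controls 1 and 2 and at 97.6 CPM in control 4. The knockouts had 265 CPM in batch A and 104 and 94.9 CPM in batch B. Over the 2000 most variable genes, the first principal component held 42.2% of the variance and parted batch A from batch B, and the next held 37.3%. With genotype in the model, 5045 genes differed between the batches (edgeR, 2461 higher and 2584 lower in batch B). Interferon-stimulated genes had a median log2 fold change of -1.35 in batch B over batch A, and oxidative phosphorylation genes one of 0.46, with camera adjusted p-values of 7.31e-05 and 7.75e-07 (adjusted p = 0.730 and 0.612 with an estimated correlation). Cholesterol biosynthesis and Th17 genes differed between the batches too, with medians of -0.36 and 0.69 in batch B over batch A. Their camera adjusted p-values were 6.69e-05 and 0.00402, and 0.612 for both with an estimated correlation. Camera at the preset correlation also called fatty acid synthesis (-0.22), amino acid and ATF4 response (-0.31), T cell activation (-0.23), p53 targets (0.38), Th2 (0.40) and NK cell markers (0.52). With an estimated correlation it called no list. Batch B holds 2 knockouts and 1 control, so the medians on genotype alone carry part of these differences.

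**Figure D2:**
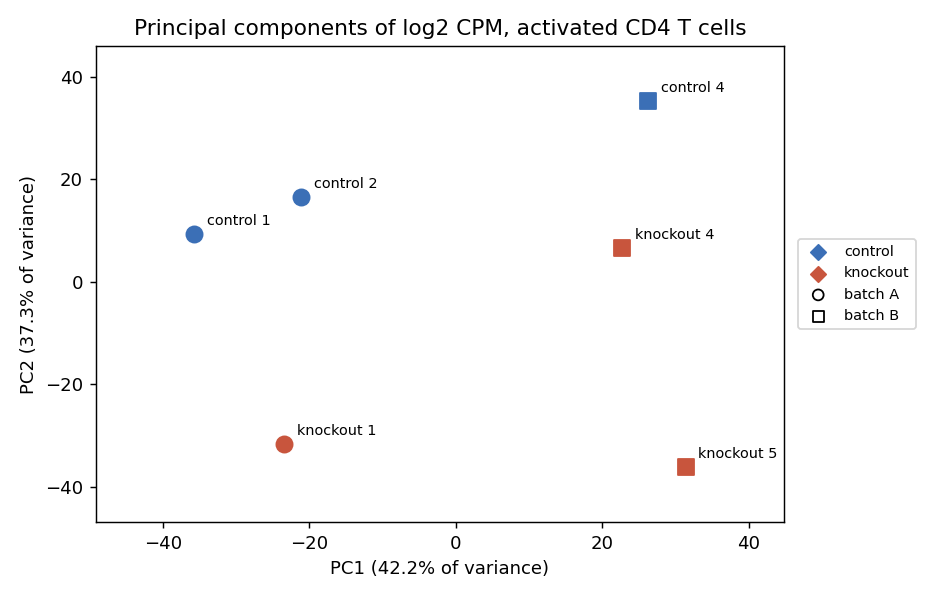
Principal components of log2 CPM for the 6 libraries, colored by genotype, with circles for batch A and squares for batch B; each axis gives its share of the variance. The first component (42.2%) separates the batches, and on the next (37.3%) every knockout lies below the controls of its own batch.

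In the batch-term fit, genes of sterol, fatty acid and amino acid synthesis were among those that fell, and some p53 targets and T helper cytokine genes among those that rose. The calls of these lists as wholes were lost by camera with an estimated correlation, in both fits. By fry, cholesterol biosynthesis, fatty acid synthesis and amino acid and ATF4 response passed in both. Their fry adjusted p-values were 0.0445 each on genotype alone, and 0.0146, 0.0468 and 0.0468 with the batch term. The p53 targets (fry adjusted p = 0.124 and 0.136) and Th17 (0.217 and 0.210) passed in neither. Sterol sensing and uptake (0.0445 and 0.0578), Th1 (0.0445 and 0.122) and Th2 (0.197 and 0.0468) passed in 1 fit each. No other list passed by fry in either fit. Glycolysis had 0.208 and 0.210, naive and quiescence 0.197 and 0.210, and G2/M and mitosis 0.320 and 0.287. The B cell markers had 0.344 and 0.287, and the NK cell markers 0.197 and 0.210. Among the largest increases with the batch term, Tnfsf4, the OX40 ligand, went from 1.92 ± 0.537 to 30.6 ± 27.0 CPM, and Phlda3, a p53 target, from 4.71 ± 2.12 to 43.4 ± 26.7 CPM (SD, n = 3). Csf2, which encodes the cytokine GM-CSF, went from 6.79 ± 3.50 to 28.7 ± 12.9 CPM. Among the largest decreases, Aldh1l2, a mitochondrial folate enzyme, went from 10.3 ± 2.14 to 1.46 ± 0.334 CPM, and Scd1, a fatty acid desaturase, from 134 ± 59.4 to 28.0 ± 21.9 CPM.

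No gene passed an adjusted p of 0.05 in the edgeR test on genotype alone, over 15685 genes, where 1780 had an unadjusted p under 0.05 (1029 higher and 751 lower in knockouts). DESeq2 called 252 higher and 190 lower genes in the same design, limma-voom 0 and 0, and limma-voom with sample quality weights 991 and 653. Once the batch was a term, edgeR called 1020 genes, 450 higher and 570 lower in knockouts. Each had the same sign inside both batches, but disagreement between the batches adds to the residual spread of that fit. A gene with opposite signs could hardly be called, so this agreement followed largely from the selection. Knockouts and controls did not overlap for 294 of the higher and 331 of the lower calls. Over all genes tested 2829 (18.0%) did not overlap. Exchangeable libraries would give 10%, but these libraries differed by batch, so the 2 shares do not measure an excess over chance. ERCC scaling with the batch term gave 77 higher and 316 lower genes, and moved the median log2 fold change of all genes from 0.02 to -0.44 (from 0.01 to -0.59 without the term). Signs that turn under ERCC scaling below follow this shift of all genes. The batch-term count varied with the library left out. It was 59 higher and 90 lower without control 1, and 1 and 2 without control 2. Without knockout 4 it was 1062 and 994, and without knockout 5 it was 437 and 556. In the fits without single libraries, 0 of the 1020 calls turned sign. These fits share most of their libraries with the full fit that selected the calls, so few signs could turn. Leaving out a library also lowers power, which was not told apart from dependence on that library. Without control 4 or without knockout 1, which leaves a batch with a single genotype, edgeR called 0 genes, with 2658 and 3507 at an unadjusted p under 0.05.

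The authors' deposited table has 954 genes with an adjusted p under 0.05 in this comparison, 493 higher and 461 lower in knockouts. Among the 14535 genes with a value in both, 221 higher and 254 lower genes were shared with the batch-term calls, and 0 were called in opposite directions. Independent lists of these sizes would share 14.1 and 17.8 genes. Both sets come from the same libraries.

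The other genes with the largest increases in the batch-term fit were Ccdc184 (log2 fold change 2.90), Zfp365 (2.45), Dglucy (2.26), Inka2 (2.23), the protease inhibitor gene Serpine2 (2.06), Psrc1 (2.04) and the p53 target Zmat3 (2.04). Other large decreases were those of the alanine transaminase gene Gpt2 (-1.93), the prolyl hydroxylase gene Egln3 (-1.85), Trib3 (-1.83), Fam198a (-1.82), the cysteine synthesis gene Cth (-1.78), the sterol reductase gene Tm7sf2 (-1.68) and the desaturase gene Fads2 (-1.67). Their edgeR adjusted p-values lay between 0.0101 for Gpt2 and 0.0463 for Egln3.

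Every measured gene of cholesterol biosynthesis was lower in knockouts on average. Msmo1, a sterol methyl oxidase, stood at 123 ± 11.6 CPM in controls and 55.9 ± 0.466 CPM in knockouts, and Lss, which closes the sterol ring, at 186 ± 22.4 and 81.4 ± 14.8 CPM (SD, n = 3). Hmgcs1, which feeds the mevalonate pathway, stood at 414 ± 144 and 187 ± 50.2 CPM, and Sqle, squalene epoxidase, at 129 ± 32.0 and 73.5 ± 21.4 CPM. The median log2 fold change of the 20 genes was -0.95 on genotype alone, and 20 of 20 were negative. The list fell by camera (adjusted p = 3.89e-33), but not with an estimated correlation (adjusted p = 0.137 with an estimated correlation). No member passed over all genes, and 17 were lower when adjusted over the list alone. In the batch-term fit the median was -0.78, 15 members fell over all genes and 18 when adjusted over the list alone (camera adjusted p = 6.24e-28; adjusted p = 0.234 with an estimated correlation). Inside batch A the median difference was -0.90 and inside batch B -0.69. The batch-term log2 fold changes of the named members were -1.08 for Msmo1, -1.11 for Lss, -0.95 for Pmvk, -0.88 for Fdft1, -0.86 for Mvd, -0.84 for Hmgcs1 and -0.59 for Sqle.

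Most fatty acid synthesis genes and some genes that sense and take up sterols were lower as well. Stard4, a sterol carrier, stood at 205 ± 6.23 CPM in controls and 115 ± 17.4 CPM in knockouts, and Insig1, which retains the sterol sensor in the endoplasmic reticulum, at 214 ± 43.3 and 112 ± 17.2 CPM. Of 12 sterol sensing and uptake genes, 9 were negative on genotype alone and 7 with the batch term, and 3 were lower when adjusted over the list alone. In the batch-term fit 4 fell over all genes, among them Stard4, Insig1 and Srebf1, and 5 when adjusted over the list alone. The list median was -0.36 (camera adjusted p = 0.000655; adjusted p = 0.137 with an estimated correlation) and -0.17 with the batch term (camera adjusted p = 0.00291; adjusted p = 0.355 with an estimated correlation), a call lost without knockouts 1 and 5, at a larger median of -0.29 (camera adjusted p = 0.0536). Srebf2 itself had a log2 fold change of -0.42 on genotype alone and 0.02 with the batch term. Among 14 fatty acid synthesis genes 13 were negative and 8 were lower when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 4.44e-13; adjusted p = 0.137 with an estimated correlation). In the batch-term fit 12 of the 14 were negative, 6 fell over all genes and 10 fell when adjusted over the list alone. The citrate carrier gene Slc25a1 fell by 1.04, Acsl3 by 0.77 and Scd1 by 1.94 on the log2 scale (list median -0.45, camera adjusted p = 6.75e-12, and 0.284 with an estimated correlation). Fasn, fatty acid synthase, had 0.18 and Acaca, an acetyl-CoA carboxylase, had -0.30 in that fit, and neither passed (edgeR adjusted p = 0.402 and 0.161). LXR targets and cholesterol efflux genes, which answer to high sterol, showed no call in either fit: the median was 0.21 on genotype alone, negative under ERCC scaling, and -0.04 with the batch term (camera adjusted p = 0.756 and 0.679). Of its 11 genes, 0 passed over all genes by edgeR in either fit, and with the batch term 1 was higher and 2 were lower when adjusted over the list alone. Abca7 had a log2 fold change of 0.46, Lpcat3 of -0.40 and Mylip of 0.49 in that fit.

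Amino acid synthesis and glycolysis moved in the same direction as the lipid genes. Trib3, a pseudokinase induced by ATF4, stood at 24.0 ± 7.30 CPM in controls and 5.59 ± 2.16 CPM in knockouts, and Psph, of serine synthesis, at 115 ± 6.35 and 62.5 ± 9.63 CPM (SD, n = 3). Ddit3, a stress-induced transcription factor, stood at 28.0 ± 3.23 and 14.1 ± 1.94 CPM. All 22 amino acid and ATF4 response genes were negative on genotype alone, 10 were lower when adjusted over the list alone, and the median was -0.69 (camera adjusted p = 6.24e-18; adjusted p = 0.137 with an estimated correlation). Of these, 8 fell over all genes with the batch term and 15 when adjusted over the list alone (median -0.53, camera adjusted p = 5.21e-14; adjusted p = 0.284 with an estimated correlation). All 20 glycolysis genes were negative in both fits. Their median was -0.41 on genotype alone, with 0 members past the threshold when adjusted over the list alone (camera adjusted p = 7.29e-10; adjusted p = 0.281 with an estimated correlation). In the batch-term fit Pdk1, which inhibits pyruvate dehydrogenase, fell by 1.23 and Pfkp, of the committed step of glycolysis, fell by 0.94. The lactate carrier gene Slc16a1 fell by 0.63. Pdk1, Pfkp and Slc16a1 were the 3 members that fell over all genes, and 13 fell when adjusted over the list alone. The list median was -0.54 (camera adjusted p = 2.1e-10, and 0.499 with an estimated correlation). The glucose carrier gene Slc2a1 had -0.73 and did not pass. Without knockouts 1 and 5 and on genotype alone, the glycolysis median was -0.10, from knockout 4 against controls mostly of batch A. Relative to the controls, the list stood at -0.090 in knockout 4 but at 0.19 in control 4, of the same batch. Inside batch A and inside batch B the median difference was -0.59. Oxidative phosphorylation was called with the batch term only, with 25 of 25 genes negative, a median of -0.23 and 1 member that fell both over all genes and when adjusted over the list alone, Ndufs3 (camera adjusted p = 0.000107; adjusted p = 0.499 with an estimated correlation). Its median on genotype alone was -0.06 (camera adjusted p = 0.147). Cox5a, Atp5d and Sdhc had batch-term log2 fold changes of -0.26, -0.23 and -0.32 and did not pass. Without knockouts 1 and 5 the batch-term call of oxidative phosphorylation ended (median -0.10, camera adjusted p = 0.273).

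A few transcripts of T helper cytokines and receptors rose in knockouts with the batch term, and most members of the Th17, Th1 and Th2 lists did not pass. Il17a, the signature cytokine of Th17 cells, was at 1.51 ± 1.46 CPM in controls and 5.63 ± 2.13 CPM in knockouts, and Il22 at 2.68 ± 3.75 and 13.3 ± 12.7 CPM (SD, n = 3). Il13, a Th2 cytokine, was at 16.3 ± 8.77 and 68.0 ± 21.8 CPM. The Th1 chemokine gene Ccl3 was at 9.03 ± 1.34 and 28.0 ± 13.6 CPM. The median log2 fold change of 17 Th17 genes was 0.73, with 15 positive and 1 higher when adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.281 with an estimated correlation). The batch-term median was 0.45, with Csf2 the single member that rose over all genes and 5 that rose when adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.499 with an estimated correlation). ERCC scaling in that fit turned the median to -0.08, which is 0.36 above the median of all genes. The batch-term call of this list was lost without control 1 (median 0.21, camera adjusted p = 0.0575), without knockout 1 (0.51, 0.127) and without knockouts 1 and 5 together (0.24, 0.244), where knockout 4 is compared with control 4 alone. Without control 4 the median on genotype alone was 1.46, and without control 1 it was 0.24; it was 0.44 without knockout 5. Il17a, Il22, Il1r1, Il23r and Ccr6 had batch-term log2 fold changes of 1.80, 1.97, 1.45, 1.15 and 1.27 and did not pass in edgeR; the smallest of their adjusted p-values was 0.0604, for Il22.

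Of 18 Th1 genes, 3 rose over all genes with the batch term: Ccl3 by 1.33, the receptor gene Cxcr3 by 0.96 and Tbx21, the lineage factor, by 0.75 on the log2 scale; 4 rose when adjusted over the list alone, against 3 on genotype alone. The Th1 median was 0.30 on genotype alone (camera adjusted p = 0.00483; adjusted p = 0.163 with an estimated correlation) and 0.32 with the batch term (camera adjusted p = 0.00687; adjusted p = 0.355 with an estimated correlation). It turned negative under ERCC scaling but stayed 0.43 and 0.32 above the median of all genes. Il18rap and Ifng had batch-term log2 fold changes of 0.96 and 0.60 and did not pass. Of 13 Th2 genes, Il13, Il5, Il9 and the lineage factor gene Gata3 rose and Nfil3 fell over all genes with the batch term; 5 rose and 2 fell when adjusted over the list alone, against 4 and 0 on genotype alone. The Th2 median was 0.28 (camera adjusted p = 0.0112; adjusted p = 0.281 with an estimated correlation) and 0.21 with the batch term (camera adjusted p = 0.0178; adjusted p = 0.355 with an estimated correlation). It also turned negative under ERCC scaling, at 0.24 and 0.18 above the median of all genes. The Th2 call was lost without control 1 on genotype alone, at a median of 0.21 (camera adjusted p = 0.0683). The batch-term call was lost at medians no smaller than in the full fit, 0.22 without control 1 (camera adjusted p = 0.0785), 0.37 without knockout 1 (0.107) and 0.23 without knockouts 1 and 5 (0.0898).

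**Figure D3:**
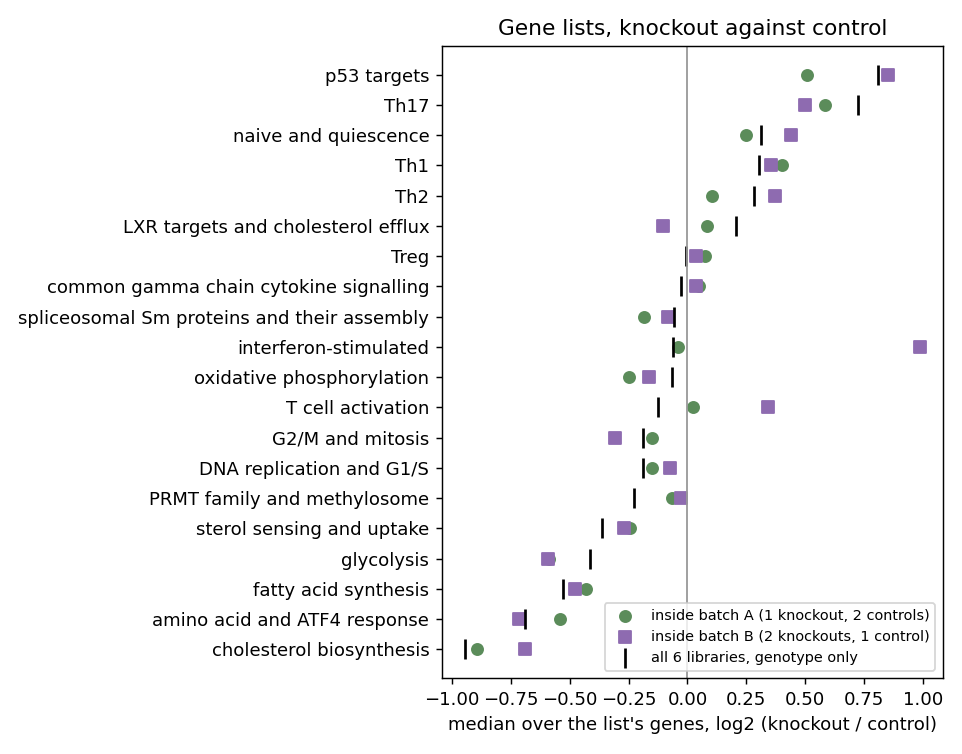
Median log2 ratio of knockout to control over the members of each functional list, from the fit of all 6 libraries on genotype alone (black bars) and from log2 CPM differences inside batch A (circles, 1 knockout and 2 controls) and batch B (squares, 2 knockouts and 1 control). Cholesterol biosynthesis lies at -0.95, -0.90 and -0.69, and the medians of Th1, Th2 and naive genes on genotype alone turn negative under ERCC scaling.

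Genes of naive and quiescent T cells were higher as a list in knockouts 1 and 5, the libraries with high B cell markers. In knockout 4 they were higher only against control 4, of its own batch. Activation and Treg genes showed no list call. S1pr1, the receptor for exit from lymph nodes, was at 18.8 ± 4.63 CPM in controls and 45.9 ± 16.3 CPM in knockouts, and Cd40lg, the CD40 ligand, at 7.88 ± 1.41 and 13.1 ± 2.12 CPM (SD, n = 3). Of 18 naive and quiescence genes, 4 rose over all genes with the batch term (Klf3, S1pr1, Dapl1 and Bach2) and 6 when adjusted over the list alone, against 0 on genotype alone; Klf2 had 1.05 and did not pass. The median was 0.31 (camera adjusted p = 0.00834; adjusted p = 0.281 with an estimated correlation) and 0.30 with the batch term (camera adjusted p = 0.000354; adjusted p = 0.499 with an estimated correlation), negative under ERCC scaling in both but 0.24 and 0.26 above the median of all genes. Relative to the controls, the list stood at 0.37 and 0.33 in knockouts 1 and 5 and at -0.18 in knockout 4, below every control. Control 4, of the same batch as knockout 4, stood at -0.096. In batch B over batch A the list had a median of -0.24 (camera adjusted p = 0.512). The median on genotype alone reversed to -0.21 without knockouts 1 and 5, where knockout 4 is compared with controls mostly of batch A. The call on genotype alone was lost without knockout 5 (median 0.27, camera adjusted p = 0.0583). With the batch term and without knockouts 1 and 5, knockout 4 is compared with control 4 alone, and the median was 0.27. Among 23 T cell activation genes, the inhibitory receptor gene Havcr2 rose by 1.87 and Cd40lg by 0.87 over all genes with the batch term, with 3 higher and 1 lower when adjusted over the list alone, against 1 and 0 on genotype alone. The activation median was -0.13 on genotype alone, where the mean was 0.04 and camera pointed upward, and 0.17 with the batch term, negative under ERCC scaling (camera adjusted p = 0.900 and 0.146). Il2, Myc and Fosl1 had batch-term log2 fold changes of -0.56, 0.26 and 0.56 and did not pass. The 16 Treg genes had medians of -0.0065 on genotype alone, where the mean was 0.18, and 0.19 with the batch term, negative under ERCC scaling (camera upward in both, adjusted p = 0.766 and 0.894), with 0 members past the threshold by edgeR over all genes or when adjusted over the list alone in either fit. Foxp3 stood at 4.64 ± 1.82 CPM in controls and 6.15 ± 4.19 CPM in knockouts, and Entpd1, Capg and Il10 had batch-term log2 fold changes of 0.55, 0.30 and 0.33. Common gamma chain cytokine signalling had medians of -0.03 in both fits (camera adjusted p = 0.625 and 0.894), and 0 of its 18 members passed by edgeR over all genes or when adjusted over the list alone in either fit. Stat5a, Il2rg and Socs2 had -0.33, 0.57 and -0.42 with the batch term.

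Targets of the tumor suppressor p53 were higher in knockouts relative to all genes. Under ERCC scaling their medians were 0.18 on genotype alone and 0.20 with the batch term. Phlda3 rose by 2.79 and Zmat3 by 2.04 on the log2 scale with the batch term, and Aen, an apoptosis-enhancing nuclease, by 0.69. Zmat3 was at 18.1 ± 2.14 CPM in controls and 76.9 ± 24.7 CPM in knockouts, and Cdkn1a, the cell cycle inhibitor p21, at 22.4 ± 15.3 and 40 ± 17.9 CPM (SD, n = 3), which did not pass. Of 25 targets, 21 were positive on genotype alone and 13 were higher when adjusted over the list alone, with a median of 0.81 (camera adjusted p = 2.78e-15; adjusted p = 0.195 with an estimated correlation). Over all genes, 8 rose and 1 fell with the batch term, and 15 rose and 2 fell when adjusted over the list alone (median 0.65, camera adjusted p = 2.13e-11; adjusted p = 0.358 with an estimated correlation). Inside batch A the median difference was 0.51, and inside batch B 0.85.

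Few cell cycle genes passed. Top2a, a topoisomerase of dividing cells, fell by 0.51 and Nusap1, a spindle protein gene, by 0.44 with the batch term, the 2 of 28 G2/M and mitosis genes past the threshold over all genes (3 fell when adjusted over the list alone, against 0 on genotype alone). The G2/M median was -0.19 (camera adjusted p = 0.00114; adjusted p = 0.545 with an estimated correlation) and -0.21 with the batch term (camera adjusted p = 0.000166; adjusted p = 0.605 with an estimated correlation). The call on genotype alone was lost without knockout 5 (median -0.11, camera adjusted p = 0.0554) and reversed without knockouts 1 and 5 (0.0098, 0.855), and the batch-term call without knockouts 1 and 5 (-0.11, 0.0744). Aurkb and Mki67 had batch-term values of -0.50 and -0.30 and did not pass. The 30 genes of DNA replication and G1/S had a median of -0.19 on genotype alone (camera adjusted p = 0.00462; adjusted p = 0.475 with an estimated correlation), lost with the batch term (median -0.11, camera adjusted p = 0.0898) and without knockout 5 (median -0.097, 0.114) or knockouts 1 and 5 (-0.062, 0.278). By edgeR 0 of them passed over all genes or when adjusted over the list alone in either fit, and Mcm7, Tk1 and Cdc45 had batch-term values of -0.48, -0.28 and -0.33.

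Genes of the arginine methylation machinery had a median of -0.23 over 12 members on genotype alone (camera adjusted p = 0.0191; adjusted p = 0.215 with an estimated correlation) and -0.06 with the batch term (camera adjusted p = 0.0319; adjusted p = 0.355 with an estimated correlation). Prmt5, the deleted gene, is itself a member and was the single gene to pass with the batch term, both over all genes and when adjusted over the list alone. Prmt6 and Prmt2 had 0.46 and 0.32 and did not pass, and both turned negative under ERCC scaling on genotype alone. The list call was lost on genotype alone without knockout 5 (median -0.093, camera adjusted p = 0.0554) or knockouts 1 and 5 (-0.21, 0.216). With the batch term it was lost without control 1 (-0.025, 0.0537), knockout 1 (-0.036, 0.138) or knockout 5 (-0.0084, 0.0605), and it reversed without knockouts 1 and 5 (0.13, 0.444). The spliceosomal Sm proteins and their assembly factors, known substrates and partners of Prmt5, had medians of -0.06 and -0.10 (camera adjusted p = 0.108 and 0.128), and by edgeR 0 of 29 passed over all genes or when adjusted over the list alone in either fit. Gemin8, Lsm10 and Snupn had batch-term values of -0.43, -0.56 and -0.47. Interferon-stimulated genes were not called on genotype alone, where the median was -0.06 and camera pointed upward (adjusted p = 0.955), and were called upward with the batch term (median 0.44, camera adjusted p = 0.0178; adjusted p = 0.728 with an estimated correlation). Their median difference was -0.04 inside batch A and 0.99 inside batch B, where control 4 is the single control; without control 4 the batch-term median was -0.07. That call was also lost without control 2 (median 0.32, camera adjusted p = 0.109) and without knockout 5 (0.23, 0.0605). Of the 25 members, 1 fell over all genes with the batch term, Dhx58, and 0 passed when adjusted over the list alone. Ddx58 and Oasl1 had 0.69 and -0.23.

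As a list, B cell markers were highest in knockouts 1 and 5, while single markers of other cell types moved apart. Relative to the controls, the B cell list median was 1.29 and 2.06 on the log2 scale in knockouts 1 and 5, -0.36 in knockout 4 and 0.52, 0.083 and -0.60 in controls 1, 2 and 4. The class II gene H2-Aa was at 19.4 and 31.5 CPM in knockouts 1 and 5 and between 5.33 and 7.24 CPM in the other libraries, but its partner H2-Ab1 was at 13.0 and 24.1 CPM in knockouts 1 and 5, 44.9 CPM in knockout 4 and 19.2, 28.0 and 56.5 CPM in controls 1, 2 and 4. In contrast to the list, Ighm, the most abundant B cell marker, was at 51.1 ± 18.9 CPM in controls and 52.5 ± 20.4 CPM in knockouts (SD, n = 3). The CD4 T cell markers had a median of 0.13 on genotype alone and 0.012 with the batch term, both negative under ERCC scaling. The B cell list median was 1.43, with 0 members past the threshold when adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.403 with an estimated correlation) and 1.28 with the batch term, where Pax5 rose over all genes and 5 of 9 rose when adjusted over the list alone (camera adjusted p = 0.000837; adjusted p = 0.499 with an estimated correlation). The NK cell list median was 1.02, with 2 higher when adjusted over the list alone (camera adjusted p = 0.000162; adjusted p = 0.281 with an estimated correlation) and 0.92 with the batch term, where Klrk1 rose over all genes and 3 of 6 rose when adjusted over the list alone (camera adjusted p = 0.00883; adjusted p = 0.499 with an estimated correlation). Without knockouts 1 and 5, which leaves knockout 4 alone, the B cell median on genotype alone reversed to -0.55. The NK cell median fell to 0.68 in that fit. The batch-term medians without them were 0.20 for B cells and -0.15 for NK cells. Without knockout 1 alone, the NK call with the batch term was lost (median 0.60, 0.305), as was the B cell call on genotype alone (1.17, 0.0503).

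Dendritic cell and CD8 T cell markers were called on genotype alone (medians 0.89 and 0.46, the latter negative under ERCC scaling but 0.53 above the median of all genes, with 2 and 1 higher when adjusted over the list alone; camera adjusted p = 0.0298 for both; adjusted p = 0.281 with an estimated correlation for both). Neither was called with the batch term (camera adjusted p = 0.135 and 0.215), where 3 and 1 members were higher and 1 and 0 lower when adjusted over the list alone. The dendritic cell call was lost without control 2, knockout 1 or knockout 5, at medians of 0.48, 0.21 and 0.29. The CD8 T cell call was lost at a smaller median without control 1 or control 2 (0.28 and 0.34) and at a larger one without knockout 1 or knockout 5 (0.73 and 0.54). With knockout 4 as the only knockout, the medians on genotype alone were 0.28 for dendritic cells and 0.57 for CD8 T cells. Platelet markers were called with the batch term alone (median 0.92, 2 of 3 higher when adjusted over the list alone, camera adjusted p = 0.0475; adjusted p = 0.499 with an estimated correlation) and lost without control 1, control 2, knockout 1 or knockout 5, at medians of 0.92, 0.76, 0.50 and 0.75. The median reversed to -0.72 without knockouts 1 and 5 (camera adjusted p = 0.602), and relative to the controls knockout 4 stood at -0.46. Macrophage and monocyte markers had medians of 0.76 and 0.97 and passed in neither fit (camera adjusted p = 0.110 and 0.173). Relative to the controls, their median was 1.79 in knockout 5, 0.61 in knockout 1 and -0.13 in knockout 4. Gzma, the most abundant NK cell marker, ranged from 6.67 CPM in control 1 to 233 CPM in control 4, with 21.8 CPM in knockout 1, and H2-Ab1, Crtam, Ly6c2, Itga2b and Pecam1, the most abundant of their lists, had batch-term log2 fold changes of -0.78, 0.37, 0.23, 1.38 and -0.12, none past the threshold in edgeR. No neutrophil or erythroid marker passed the count filter, and 2 stroma and endothelium markers did, too few for a list test.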

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

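The fits with the batch term, inside each batch, with ERCC scaling and without knockouts 1 and 5 were chosen after the data were seen; the other alternatives were planned. Where a value differs below, the cause was not tested unless stated. The replicate numbers 1 and 4 occur in both genotypes, but nothing ties a number to a shared animal or day; deviations from the group means correlated at 0.58 and 0.43 for these pairs and at 0.40 and 0.41 for the other control and knockout pairs of a batch. With the replicate block, which rests on those pairs, edgeR called 333 higher and 435 lower genes and Prmt5 had -1.61, and the PRMT family median was 0.00084, the dendritic cell median -0.0046, Ighm -0.014 and Myc 0.21.

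On genotype alone the count of 0 higher and 0 lower genes stayed at 0 with limma-voom, RLE and upper-quartile factors and the stricter filter. It also stayed at 0 in the 1.5-fold test, at the 0.01 threshold and with each library left out (0 to 0), where fewer samples were fitted. It was 252 higher and 190 lower with DESeq2, 493 and 227 with no low-count filter, 991 and 653 with quality weights, 61 and 212 with ERCC scaling, 450 and 570 with the batch term and 1091 and 1111 inside batch A. Prmt5 passed in the same settings, at -1.71 (DESeq2), -1.73 (no filter), -1.87 (quality weights), -2.35 (ERCC scaling) and -1.58 (batch term), and ranged from -1.84 to -1.64 without single libraries. It was at -1.70 inside batch A, with 1 knockout, and at -1.49 inside batch B, with 1 control. Counts of genes from the fits inside a batch are not given, because 1 genotype has no replicate there. Inside batch A the spread rests on controls 1 and 2 alone, the most alike pair.

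With the batch term, 450 higher and 570 lower genes became 1096 and 1282 with DESeq2, 1552 and 1392 with no filter, 77 and 316 with ERCC scaling, 1 and 2 in the 1.5-fold test and 2 and 4 at the 0.01 threshold. Without knockouts 1 and 5 there were 741 higher genes and 770 lower, but this leaves batch A with controls only, so that knockout 4 is compared with control 4 alone and the spread rests on controls 1 and 2, the most alike pair; these counts do not bear on whether the calls recur. Without single libraries the counts ran from 0 to 1062 higher and from 0 to 994 lower, and Prmt5 from -1.70 to -1.49, with edgeR adjusted p-values of 0.0601 without control 4 and 0.0707 without knockout 1. DESeq2 called 980 of the 1020 genes again and limma-voom 961. ERCC scaling called 229 again, and 23 of the 1020 had the opposite sign there. Without control 1 or control 2, 144 and 3 were called again, and without control 4 or knockout 1, 0. Without knockout 4 or knockout 5, 988 and 812 were called again.

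The cholesterol biosynthesis median stayed negative in every setting run, from -1.08 to -0.86 without single libraries and from -0.91 to -0.71 with the batch term; its call was lost only with an estimated correlation, at the same medians of -0.95 and -0.78. The Th17 median ranged from 0.24 to 1.46 and, with the batch term, from 0.21 to 0.79 without single libraries. Its call was lost with an estimated correlation and with fry, at 0.73 and 0.45, and with the batch term also with DESeq2 (0.45), limma-voom (0.41), quality weights (0.59) and without knockouts 1 and 5 (0.24), and its median reversed with ERCC scaling (-0.076).

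Other sign changes are given next. With ERCC scaling, which lowered the median of all genes and turned signs by that shift, the medians were -0.17 (Th1), -0.35 (Th2), -0.35 (naive and quiescence) and -0.063 (CD8 T cell), with the batch term -0.12 (Th1), -0.26 (Th2) and -0.18 (naive and quiescence), and single genes were at -0.24 (Prmt6), -0.044 (Prmt2), -0.23 (Mylip), -0.061 (Fosl1), -0.21 (Il2rg), -0.063 (Crtam), -0.63 (Ighm), -0.36 (Ly6c2), -0.057 (Tbx21), -0.35 (Gata3), -0.34 (Bach2) and -0.25 (Foxp3). Inside batch A, Il10 was at -0.37, Srebf2 at 0.014 and Myc at 0.14. Inside batch B, Oasl1 was at 0.99, Crtam at -0.018, Gzma at -0.24, Ly6c2 at -0.045, Srebf2 at 0.0070, Il2 at 0.25 and Myc at 0.36. With the batch term, Gzma was at -0.055, Srebf2 at 0.024 and Myc at 0.26. Without knockouts 1 and 5, which leaves a single knockout assumed to vary like the controls, the medians were -0.21 (naive and quiescence), 0.0098 (G2/M and mitosis) and -0.55 (B cell), with the batch term 0.13 (PRMT family), -0.15 (NK cell) and -0.72 (platelet), and genes were at -0.20 (Klf2), -0.73 (Ighm), 0.38 (H2-Ab1), -0.20 (Gata3), 0.085 (Nfil3), -0.69 (Klf3), -0.42 (Bach2), 0.020 (Nusap1), 0.068 (Ndufs3), -0.53 (Pax5) and -0.78 (Foxp3). With quality weights Ighm was at -0.29, H2-Ab1 at 0.16, Pecam1 at 0.11, Gata3 at -0.028, Klf3 at -0.11, Bach2 at -0.18, Nusap1 at 0.15, Ndufs3 at 0.17 and Foxp3 at -0.22. Pecam1 was at 0.0024 with the stricter filter and 0.011 with upper-quartile factors. Without control 1, Myc was at 0.16; without control 4, Ighm was at -0.22, H2-Ab1 at 0.21, Pecam1 at 0.11, Nusap1 at 0.085, Ndufs3 at 0.097 and the batch-term interferon-stimulated median at -0.070; the other ends of the ranges without single libraries were 0.32 (Ighm), -0.13 (Pecam1), 1.39 (Klf3), 0.62 (Bach2), -0.39 (Nusap1), -0.33 (Ndufs3), 0.76 (Foxp3) and 1.03 (interferon-stimulated, batch term). Without knockout 1, Ighm was at -0.26, Pecam1 at 0.050, Klf3 at -0.018, Bach2 at -0.20 and Foxp3 at -0.30; without knockout 5, Ighm was at -0.0078 and Myc at 0.03. Depth limits the low genes: Ccr6 and Il1r1 rest on about 1 CPM or less in controls.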

Other observations

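Tests in this part were chosen after the result they bear on had been seen, with 3 exceptions. These are the gene length test over all genes, the camera test of the sex list on genotype alone and the splits on genotype alone. Reading those splits by batch was chosen afterwards. Y-linked genes parted the libraries in a way the genotype labels do not. Kdm5d, Uty, Ddx3y and Eif2s3y had 0 CPM in control 1 and knockout 4, while Ddx3y was at 72.3 CPM in control 2, 49.9 in control 4, 28.6 in knockout 1 and 75.9 in knockout 5. Xist, from the inactive X chromosome of females, was at 778, 454 and 621 CPM in controls 1, 2 and 4 and at 1157, 1298 and 767 CPM in knockouts 1, 4 and 5, so that 4 libraries held both Xist and Y-linked RNA. The sex list had a median of -0.23 on genotype alone and -0.37 with the batch term, where camera pointed upward (adjusted p = 0.625 and 0.731).

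Genes that differed between the batches were of unlike length. The 2584 genes lower in batch B had a median length of 3981 bp in the deposited table and the 2461 genes higher in batch B one of 2442 bp, against 2867 bp over all genes tested. Spike-in RNA made up 0.817 ± 0.239% of the counts in controls and 1.20 ± 0.174% in knockouts (SD, n = 3, exact permutation test, p = 0.2, where the smallest possible is 0.1).

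The edgeR fit on genotype alone called 0 genes and the fit with the batch term called 1020. All 10 splits of the 6 libraries into 3 and 3 meet a real count of 0 by construction, so comparing them with it tests nothing. The split by batch gave 2080 genes, and the highest of the remaining splits gave 0. That points to a structure of the libraries that follows the batch tag and may widen the spread within each genotype. With the batch term, 1 of 9 labelings that keep the make-up of each batch gave as many genes, the real one, and the highest other gave 0; splits this few, in either fit, cannot give a share under 0.05. A length bias between the genotypes stays open: length and the batch-term log2 fold change had a Spearman correlation of 0.0745 over all genes, a set that dilutes the called genes, and of 0.13 over the 1020 called genes, whose median lengths were 3631.5 bp (higher) and 2817.5 bp (lower). Genes are not independent replicates.

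The lower cholesterol biosynthesis list could come from other cells diluting T cell RNA, from the batches, from fewer dividing cells or from loss of Prmt5. Dilution is argued against by the CD4 T cell markers, whose median log2 fold change was 0.13 (SD of the members 0.14) against -0.95 for the list. The batches as the whole cause are argued against by a median difference of -0.69 inside the batch with the smaller difference, where the same-genotype libraries, knockouts 4 and 5, differed by 0.13. Fewer dividing cells as the whole cause are argued against by a G2/M median of -0.19 (SD of the members 0.15), provided that such a loss lowers both lists alike, which was not tested. Relative to the controls, the G2/M list stood at -0.22, 0.029 and -0.36 in knockouts 1, 4 and 5. The cholesterol biosynthesis list stood at -0.69, -0.97 and -1.11 there. The SDs given here are over genes that move together and do not measure the spread between animals. An effect of Prmt5 loss on sterol gene expression stays open as a hypothesis, as does a difference between the animals in any factor that the labels do not give.

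The higher B cell markers may come from B cells left in the isolates of knockouts 1 and 5, and the B cell and NK cell markers from a lower share of CD4 T cells there; NK cells, CD8 T cells and macrophages in the isolates were not tested. Against their batch mates, the 9 B cell markers were higher by a median of 1.63 in knockout 1 and 2.59 in knockout 5, but Ighm, the most abundant, by 0.25 and 0.83. Ighm had a baseline of 51.1 CPM in controls that can hide a small share of B cells, so B cells cannot be told apart from a change in the T cells themselves. The CD4 T cell markers had a median of 0.012 with the batch term, and a loss of a few percent of these cells would not be seen in it. Purity of the isolates was not analysed here, and the Th17 call with the batch term was lost without these libraries (median 0.24), where knockout 4 is compared with control 4 alone.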
